A study of Homo sapiens with 6 samples.

How the data were processed

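Single-cell messenger RNA was measured by Drop-seq in 6 libraries of the human cell line PC9, 1 per condition. The deposited tables hold counts: whole numbers of UMIs per gene symbol and cell barcode, with no normalization, as the values themselves showed. According to the submitters' processing notes, the authors used STAR and FastQC with the genome build GRCh37.p13, or hg19. The labels give neither versions nor settings, nor the counting tool or the choice of barcodes. Genes were taken by the symbols in the files, 26195 over all 6 libraries. A GRCh38 annotation (GENCODE) was used for 1 purpose, the type of each gene by its symbol. It matched 18052 symbols, or 68.9%, which carried between 93.1% and 95.1% of UMIs, so processed pseudogenes without a matching symbol are missing from their share. No coordinates are given, since the builds differ.

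Per the labels, 4 libraries received 2 µM erlotinib for 1 day together with CPI-455 (6.25 µM, 4 days), KDM5A shRNA, both KDM5A and KDM5B shRNA, or KDM5A cDNA. The controls were scrambled shRNA and untreated cells, both without erlotinib. The shRNA vectors were pLVTHM and the cDNA vector pLenti. The labels date erlotinib in the CPI-455 library both to the day after seeding and to 1 day of treatment, which leaves its timing within the 4 days open. The labels give no sequencing batch or date.

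Barcodes were kept as cells with at least 500 UMIs and at most 20% of UMIs from mitochondrial transcripts. This kept 202 of 599 barcodes with CPI-455, 374 of 663 with KDM5A shRNA, 152 of 604 with KDM5A and KDM5B shRNA, 131 of 723 with KDM5A cDNA, 263 of 706 in the scrambled library and 1166 of 2500 in the untreated library. Of barcodes with at least 500 UMIs, 17.8% exceeded the mitochondrial limit in the KDM5A and KDM5B shRNA library, 9.03% with KDM5A cDNA and between 0.766% and 2.42% in the others. Barcodes under 500 UMIs held between 2.63% and 7.35% of all UMIs. No doublet caller was used, since doublets of a single line look alike. UMIs were summed over the kept cells of each library, and levels are given in CPM, the usual scaling of counts to a fixed total per library. Depth limits precision: 3 counts, the floor used for a count of 0, correspond to between 0.758 and 5.08 CPM. Intervals and floors cover counting error only.

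Erlotinib was tested on the summed counts with edgeR 4.0.16 (TMM, filterByExpr on erlotinib, robust quasi-likelihood fit and test, Benjamini-Hochberg adjusted p under 0.05), with 4 libraries against 2 and a common coefficient of biological variation of 0.262. The 4 libraries are not replicates of a single condition, and their KDM5 manipulations enter the spread. The p-values therefore compare erlotinib together with some KDM5 manipulation against its absence, relative to the spread among these libraries. Standard errors of log2 folds were derived from the fold and its F statistic. Gene lists were tested with camera in limma 3.58.1 at the preset correlation of 0.01 and with an estimated correlation, over the lists with a tested member. Fitted folds of genes at 0 in a group depend on the prior count, so such genes carry a bound against 3 counts over the group. Pooled ratios of the erlotinib groups are of UMIs summed over libraries and so weight deeper libraries more.

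Between 2 libraries no test was run. The log2 ratio of CPM has the exact 95% interval of a ratio of 2 Poisson counts (conditional Clopper-Pearson). List medians take members with at least 10 UMIs over both libraries, with 0.5 added to each count, and are ranked as a percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. A second median places genes at 0 at their bound. The 8 planned pairs set the transduced arms against the scrambled library, CPI-455 and the scrambled library against the untreated library, and pairs of erlotinib libraries against each other. Shares of cells with list UMIs were taken after thinning each cell to 1000 UMIs, with exact binomial intervals, and shallower cells were left out. Variation between cells was the variance above the mean divided by the squared mean. Correlations of ratios across genes used genes at 50 CPM or more.

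Which genes are named, the lists, filters, comparisons and most alternatives were fixed before the data were examined. For erlotinib they are KDM5A, KDM5B and EGFR, then the 12 genes with the largest positive and the 12 with the largest negative fold among called genes with every erlotinib library on the same side of both controls. KDM5C was also on that list and is not analysed here. A few genes that these rules select are not reported here. For each pair of libraries they are the 10 highest and the 10 lowest by the bound of the interval nearest 0, among genes at 50 CPM or more in either library, and the text names part of them. Within the 31 lists they are up to 4 members with the most counts, and for variation the 15 highest in untreated cells.

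Before the data were examined, alternatives were set for the tool (DESeq2 1.42.0, limma-voom), the normalization, the low-count filter, the cell filter, leaving out each library, high-UMI cells, thinning, weighting, the control library, list minimums and share thresholds. Added after the data were seen were the pseudogene split of the libraries at 2% of UMIs as a term, with 2 more pairs of libraries on its high side, a share at 10 list UMIs, and thinning and high-UMI cells for the erlotinib counts. The steps were tested on simulated data. In 5 simulations with 200 of 10445 genes changed, the erlotinib test recovered 0.800% of 1.5-fold changes, 12.8% of 2-fold, 72.0% of 4-fold and 95.6% of 8-fold, and 48 of 501 calls were false (9.58%), above the nominal 5%. The real test called 2458 genes. Recovery and the false share depend on how many genes change, so these values may not carry over to it. The intervals of pairs held the true ratio for 96.5% of 10016 genes, and 5.50% of unshifted lists passed the 95th percentile. These simulated counts were independent Poisson draws and the lists were randomly drawn genes. UMIs gathered in few cells and correlation between list members were therefore not tried. Percentiles among random lists do not allow for such correlation. Set variation of 0.5 and 1 was returned as 0.478 and 0.964. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.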

Results

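The series measured messenger RNA in single cells of PC9, an established human lung adenocarcinoma line with an activating EGFR mutation. Transcripts were captured by Drop-seq, a droplet method that tags each molecule with a unique molecular identifier (UMI). Each of 6 conditions had 1 library. Cells were untreated, or carried a lentivirus with a scrambled shRNA, and both of these were without drug. The other 4 libraries were given 2 µM erlotinib, an inhibitor of the EGFR kinase, for 1 day. They also received either CPI-455, an inhibitor of the KDM5 histone demethylases, at 6.25 µM for 4 days, or lentiviruses encoding KDM5A shRNA, KDM5A and KDM5B shRNA, or KDM5A cDNA. Erlotinib started 4, 5 and 6 days after transduction in these 3 transduced libraries, in that order. Each library is named below by its KDM5 manipulation, and no library had erlotinib without such a manipulation.

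Kept cells numbered 1166 in the untreated library, 263 in the scrambled library, 202 with CPI-455, 374 with KDM5A shRNA, 152 with KDM5A and KDM5B shRNA and 131 with KDM5A cDNA. In the same order these cells held 3956647, 1294422, 873760, 1596385, 725788 and 590091 UMIs. The median per cell was 1493.5 UMIs in the untreated library and between 2985.5 and 3762.5 in the others. A count of 0 allowed a level of up to 0.758 CPM (counts scaled to a fixed library total) in the untreated library and up to 5.08 CPM in the KDM5A cDNA library, at 3 counts. Mitochondrial transcripts made up 3.98% of UMIs in untreated cells, 5.03% in scrambled cells and between 7.04% and 9.18% in the 4 erlotinib libraries. Processed pseudogenes, the intronless copies of other genes, took 2.77%, 2.38% and 3.25% of UMIs in the CPI-455, the KDM5A and KDM5B shRNA and the KDM5A cDNA libraries, against 1.25% with KDM5A shRNA, 1.31% with the scrambled vector and 0.956% untreated. This split ran across the conditions, so its values stand beside the comparisons that cross it. With 1 library per condition, no condition was tested against another. Ratios between libraries carry exact 95% intervals for counting error only, and "higher" and "lower" there describe these libraries.

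The first question was whether the KDM5 transcripts followed the labels. KDM5A, which encodes a histone lysine demethylase, stood at 56.4 CPM (95% interval 45.3 to 69.3) with KDM5A shRNA and 41.3 CPM (27.9 to 59.0) with KDM5A and KDM5B shRNA. It stood at 81.9 CPM (67.0 to 99.0) in scrambled cells and 164 CPM (133 to 200.5) with KDM5A cDNA. Against the scrambled library the ratios were 0.688 (0.514 to 0.920), 0.505 (0.325 to 0.763) and 2.01 (1.51 to 2.67). Counts come from transcript ends, so a cDNA without the untranslated region at that end may not be counted. The 164 CPM may therefore not hold all KDM5A transcripts of that library. The untreated and CPI-455 libraries held 121 and 120.2 CPM, a ratio of 0.993 (0.796 to 1.23), and the scrambled library lay below the untreated library at 0.676 (0.543 to 0.836). KDM5B, a related demethylase, was not lower in the library whose label names its shRNA. It stood there at 138 CPM (112 to 168), 2.97 times the scrambled level (2.14 to 4.16) and 0.913 times that with KDM5A shRNA alone (0.715 to 1.16). Directions for the library labelled KDM5A and KDM5B shRNA are therefore those of a library with high KDM5B. EGFR, the target of erlotinib, lay between 273 and 350.0 CPM in all 6 libraries. With every cell thinned to 1000 UMIs, KDM5A with KDM5A shRNA against scrambled turned to a log2 ratio of 0.30 (-0.73 to 1.40), from 24 and 13 UMIs, and with KDM5A and KDM5B shRNA it was -0.28 (-1.96 to 1.22), from 6 and 13 UMIs.

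**Figure D1:**
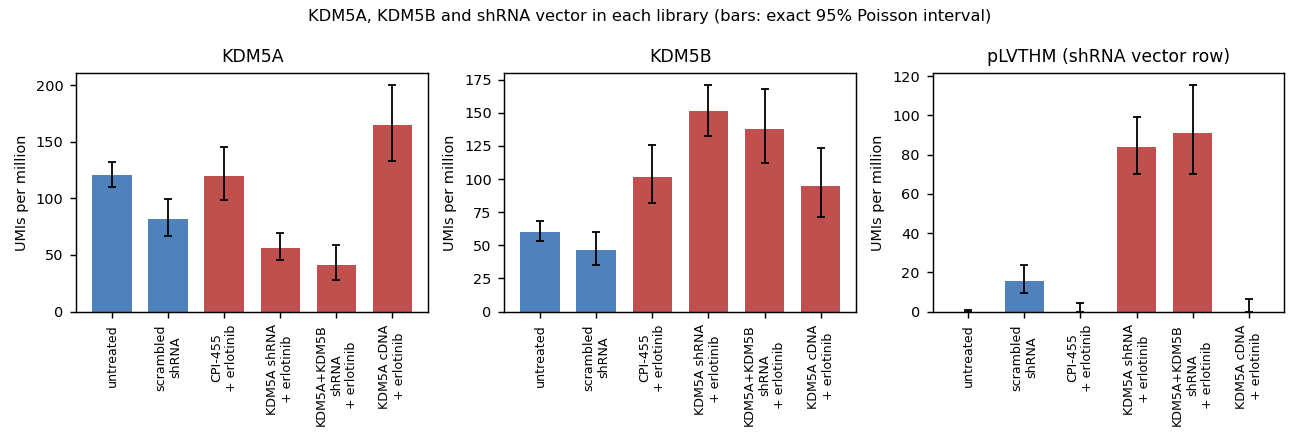
Levels of KDM5A, KDM5B and the transcript of the shRNA vector pLVTHM in CPM over the kept cells in each of the 6 libraries, 1 library per condition, with exact 95% Poisson intervals for counting error only. KDM5A runs from 41.3 CPM with KDM5A and KDM5B shRNA to 164 CPM with KDM5A cDNA, and KDM5B is above both drug-free libraries in all 4 erlotinib libraries.

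The next comparison asked what the 4 erlotinib libraries shared against the 2 without the drug. Genes of DNA replication and mitosis fell. All 42 tested members of the S phase list fell, and 42 did so adjusted over the list alone. Among them, in edgeR, were PCNA, the sliding clamp of DNA polymerase, with a log2 fold of -4.03 (SE 0.23, adjusted p = 2.96e-05), and TYMS, which makes thymidylate, with -4.26 (SE 0.45, adjusted p = 0.000413). Of 50 G2/M genes 44 fell (49 adjusted over the list alone), among them SMC4, a condensin subunit, at -3.22 (SE 0.29, edgeR adjusted p = 0.000109). Of 13 genes of MAPK output, the signalling arm below EGFR, 10 fell and none rose (10 lower and 1 higher adjusted over the list alone). CCND1, or cyclin D1, fell by 2.27 on the log2 scale (SE 0.46, edgeR adjusted p = 0.0107) and PHLDA1 fell by 3.22 (SE 0.36, edgeR adjusted p = 0.000317). MYC stood at -0.01 (SE 0.25, edgeR adjusted p = 0.983) and EGR1 at 2.23 (SE 0.88, edgeR adjusted p = 0.105), so neither passed. The set test camera called these 3 lists lower at its preset correlation of 0.01, but adjusted p was 0.256, 0.407 and 0.256 with an estimated correlation. In this and the following paragraphs on erlotinib, every gene with a log2 fold that passed had all 4 erlotinib libraries on the same side of both libraries without the drug.

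Inflammatory and quiescence genes were among those that rose with erlotinib, but the CPI-455 library stood apart for the former. Of 15 tested NF-kB and inflammatory genes 9 rose and none fell (11 and 0 adjusted over the list alone), among them NFKBIA, the feedback inhibitor of NF-kB, at a log2 fold of 2.70 (SE 0.47, edgeR adjusted p = 0.00418), and the adhesion molecule ICAM1 at 3.47 (SE 0.60, edgeR adjusted p = 0.00480). Against untreated cells the NF-kB list had a median log2 ratio of 0.23 with CPI-455, with 7 members above and 6 below 0, while the transduced erlotinib libraries had medians of 2.88 to 3.42 against scrambled. TNFAIP2, induced by tumour necrosis factor, stood at 80.1 CPM with CPI-455, below both drug-free libraries at 98.1 and 139 CPM. Of 11 FOXO and quiescence genes 8 rose (9 adjusted over the list alone), with YPEL3 at 2.83 (SE 0.33), YPEL5 at 2.33 (SE 0.31) and the antiproliferative gene BTG1 at 1.06 (SE 0.21). Of 14 interferon response genes 7 rose (8 adjusted over the list alone). IRF1, an interferon-induced transcription factor, stood at 2.50 (SE 0.27, edgeR adjusted p = 0.000305), while ISG15, an interferon-induced modifier, did not pass at 0.37 (SE 0.33, edgeR adjusted p = 0.434). These lists also passed camera at the preset correlation, with adjusted p = 0.508, 0.407 and 0.256 with an estimated correlation. KDM5B rose by 1.23 (SE 0.26, edgeR adjusted p = 0.00883), KDM5A stood at -0.08 (SE 0.48, edgeR adjusted p = 0.923) and EGFR at -0.15 (SE 0.19, edgeR adjusted p = 0.594).

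The genes with the largest fitted increases included a serum amyloid, chemokines and a keratin. SAA2, an acute-phase serum amyloid, had 306 UMIs with erlotinib and 0 without, at least 141-fold higher over the group, with 106 and 164 CPM in the KDM5A shRNA and the KDM5A and KDM5B shRNA libraries but 9.16 with CPI-455 and 16.9 with KDM5A cDNA. The neutrophil chemokines CXCL6 and CXCL3, also at 0 without the drug, were at least 17.6-fold and 12.5-fold higher over the group, but each had 1 UMI with CPI-455 and 1 with KDM5A cDNA, below the floors of 3.43 and 5.08 CPM, so these bounds rest on the shRNA libraries. CXCL1, of the same family, had 145 UMIs against 2, a pooled ratio of 101 (95% counting interval 27.3 to 838), with 71.4 and 26.2 CPM in the shRNA libraries, 18.6 with KDM5A cDNA and 1.14, or 1 UMI, with CPI-455. PDZK1IP1, a small membrane protein, had a pooled ratio of 266 (135 to 618), from 627 and 679 CPM in the shRNA libraries against 19.5 with CPI-455 and 40.7 with KDM5A cDNA. The matrix protease MMP7 had 113 (38.1 to 551), from 94.0 and 114 CPM against 8.01 and 6.78. Pooled ratios weight the deep KDM5A shRNA library most. KRT17, a keratin of basal epithelium, stood between 258 and 2716 CPM with erlotinib against 32.4 and 40.7 CPM without, a pooled ratio of 44.2 (38.4 to 51.1), with a fitted log2 fold of 5.33 (SE 1.14, edgeR adjusted p = 0.0191). GABRP, NEURL3, ANKRD34B, OLR1 and AC069213.1 completed this group, with pooled ratios between 38.4 and 118. The largest fitted decreases included regulators of DNA replication. MCM10, a replication initiation factor, had 0 UMIs in all 4 erlotinib libraries and 289 in the others, at least 69.5-fold lower. E2F1 and E2F2, activators of S phase genes, and the phosphatase CDC25A were also at 0 and at least 35.3-fold, 12.7-fold and 25.7-fold lower. CDC6, which loads the replicative helicase, had 2 UMIs against 410, a 148-fold difference (40.7 to 1225), and CLSPN, a checkpoint adaptor, was 93.0-fold lower (45.0 to 232). CDCA7, FAM111B, CDC45, DTL and EXO1 were between 92.3-fold and 221-fold lower by pooled UMIs.

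Other lists moved in part, and the number in parentheses after each count is that adjusted over the list alone. Of 13 mitochondrial transcripts 5 rose (9), with MT-CO1, a subunit of cytochrome oxidase, at 1.39 (SE 0.25, edgeR adjusted p = 0.00362). Of 13 epithelial genes 6 rose (7), of 16 YAP and TGF-beta targets 7 (9), of 18 lysosome and autophagy genes 7 (9), of 12 immediate early genes 4 (4), of 8 mesenchymal genes 3 (4) and of 13 NRF2 targets 3 (3). Examples were FN1, or fibronectin, at 3.44 (SE 0.88), FOS, an AP-1 subunit, at 2.61 (SE 0.54), PSAP, a lysosomal precursor, at 1.18 (SE 0.28) and the ferritin chain FTH1 at 1.45 (SE 0.22). Of 12 glycolysis genes 6 fell (9), among them ENO1 at -1.10 (SE 0.23), and 8 of 36 oxidative phosphorylation genes fell (8). Of 10 heat shock genes 4 fell (5), among them the chaperone HSP90AA1 at -1.23 (SE 0.19), and 1 rose (1), HSPB1 at 1.45 (SE 0.39). Of 21 cholesterol synthesis genes 2 fell (1) and of 10 fatty acid synthesis genes 1 fell (1). Camera called these 12 lists at the preset correlation, with adjusted p between 0.508 and 0.673 with an estimated correlation. With 1 library left out, the preset adjusted p reached 0.382 for cholesterol synthesis, 0.807 for fatty acid synthesis, 0.132 for oxidative phosphorylation and 0.131 for mesenchymal genes, each without the untreated library, 0.153 for heat shock without the scrambled library and 0.151 for NRF2 targets without the KDM5A cDNA library. The other lists were not called. Of 15 genes of the drug tolerance literature 6 rose (8) and 2 fell (3), with IGFBP3 at 3.29 (SE 0.53). In the remaining lists the counts higher and lower were 1 and 0 of 2 KDM5 genes (1 and 0), 0 and 1 of 4 ERBB receptors and ligands (2 and 1), 1 and 0 of 3 antigen presentation genes (1 and 0), 2 and 1 of 14 p53 targets (2 and 1), 1 and 0 of 19 stress response genes (0 and 0), 3 and 2 of 9 hypoxia genes (4 and 2), 0 and 0 of 2 alveolar genes (0 and 0), 1 and 1 of 36 cytoplasmic ribosomal proteins (0 and 0), 0 and 1 of 4 metallothioneins (0 and 1) and 2 and 1 of 11 apoptosis regulators (2 and 1). The ERBB list had a median of 0.35 and a mean of -0.40, and the ribosomal list a median of -0.0002 and a mean of 0.0007, with camera directions of up for both.

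In all, edgeR called 1046 genes higher and 1412 lower of 10445 tested, and 1017 and 1409 of these had all 4 erlotinib libraries on the same side of both others. With the pseudogene split as a term, all called genes kept their sign. Every library on the high side of that split had erlotinib. That fit therefore set KDM5A shRNA alone against the scrambled and untreated libraries, and calls lost in it cannot be assigned to pseudogenes. Several other fits gave smaller counts. They were 520 and 899 without the KDM5A and KDM5B shRNA library, 639 and 860 without the scrambled library, 500 higher without the untreated library, 479 and 856 in transduced libraries only, and 473 and 509 with cells thinned to 1000 UMIs. The calls of SAA2, PDZK1IP1, CXCL6, MMP7 and KRT17 ended with the split as a term. With limma-voom those of ANKRD34B, CXCL1, MMP7, NEURL3, OLR1, PDZK1IP1 and SAA2 ended, with RLE size factors those of PDZK1IP1 and SAA2, and with all barcodes that of PDZK1IP1. Without the untreated library those of 10 of the 12 genes with the largest increases ended, and without the scrambled library those of the same 10 and KDM5B. The calls of PDZK1IP1 and SAA2 ended without the KDM5A shRNA library, those of PDZK1IP1 and CXCL1 without the KDM5A and KDM5B shRNA library, and that of CXCL1 without the KDM5A cDNA library. CXCL3, CXCL6 and ANKRD34B were no longer tested when either shRNA library was left out, nor were MMP7 and E2F2 when it was the KDM5A shRNA library, nor E2F2 when either drug-free library was left out.

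**Figure D2:**
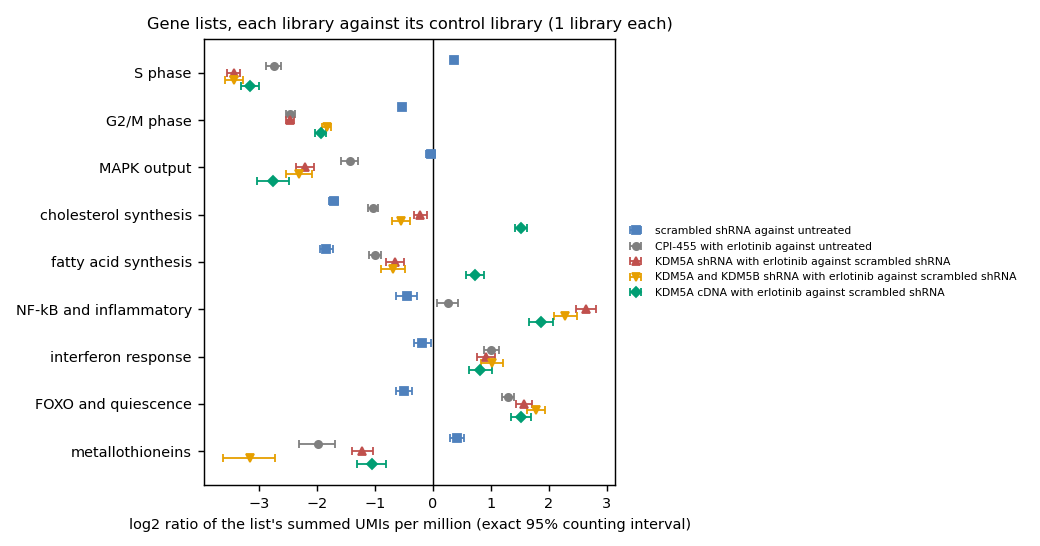
Pooled log2 ratio of CPM for 9 of the fixed gene lists in 5 pairs of a library and its control, with exact 95% counting intervals and a line at 0, 1 library on each side of a pair. The S phase and G2/M lists lie below 0 in every erlotinib library against its control, and the cholesterol synthesis list lies below 0 for scrambled against untreated at -1.71 and above 0 for KDM5A cDNA against scrambled at 1.52.

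The scrambled library was set against the untreated library to show what the control virus and its culture carried. Lipid synthesis genes were lower in scrambled cells: the cholesterol synthesis list had a median log2 ratio of -2.11, with 21 of 22 members below 0, and a pooled ratio of -1.71 (-1.80 to -1.63). The fatty acid synthesis list had a median of -1.78, with 9 of 10 below 0. SCD, the stearoyl-CoA desaturase, stood at 12.4 against 276 CPM, a log2 ratio of -4.48 (-5.30 to -3.78) and FADS2, another desaturase, at -4.02 (-4.65 to -3.45). G2/M genes had a median of -0.65, with 47 of 51 below 0, while S phase genes had 0.35, with 36 of 42 above 0. FOXO and quiescence genes had a median of -1.01 and immediate early genes -0.86, with JUND, an AP-1 subunit, at -3.11 (-3.88 to -2.44). The nuclear RNA MALAT1 was at -2.27 (-2.34 to -2.19). The genes ranked highest were mostly pseudogene copies, such as KRT18P67 at 3.51 (2.79 to 4.27) and FTH1P4 at 2.59 (2.19 to 3.01). The 4 lipid and cycle medians named first lay outside all 10000 random lists matched on expression, as did that of the FOXO list, and the immediate early median lay at the percentile 0.130. Transduced cells were cultured in 10% serum after transduction and the others in 5%, so virus and medium went together. The untreated library differed in its barcodes as well: 41 of 1166 kept barcodes ended in the letter N, against 60 of 263 scrambled ones. Median UMIs per cell were 1493.5 and 3343. A technical difference can therefore not be told apart from virus and medium.

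CPI-455 with erlotinib was set against untreated cells, the other condition without virus. Cycle genes were lower in the CPI-455 library: all 51 G2/M genes lay below 0, with a median of -2.58, and all 42 S phase genes, with a median of -3.36, or -2.96 with genes at 0 placed at their bound. HELLS, a chromatin remodeller of S phase, had 0 UMIs against 450, at least 33.1-fold lower, and TOP2A, the mitotic topoisomerase, stood at -4.10 (-4.62 to -3.62). MAPK output had a median of -3.12, with 13 of 15 below 0. FOXO and quiescence genes had a median of 1.01, with all 13 above 0, mitochondrial transcripts 0.96, interferon response 0.89, immediate early genes 0.89 and YAP and TGF-beta targets 0.82. The NF-kB list stood at 0.23, above 74.8% of random lists. Single genes included GNG10, a G protein subunit, at 6.73 (4.80 to 9.82, 47 against 2 UMIs), STEAP4, a metalloreductase, at 4.59 (3.72 to 5.57), and TGM2, or transglutaminase, at -4.48 (-5.61 to -3.54). Pseudogene copies were also among the genes ranked highest, such as KRT18P67 at 4.61 (3.93 to 5.35) and FTH1P4 at 4.16 (3.79 to 4.53). Both of these also ranked highest for scrambled against untreated. The other lists named here lay outside at least 99.9% of random lists. The median of cholesterol synthesis was -1.06 and that of fatty acid synthesis -1.04, but against the scrambled library they were 0.80 and 0.73. The pair crosses the pseudogene split (2.77% against 0.956% of UMIs), and on the high side no library was without erlotinib.

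KDM5A shRNA with erlotinib was set against the scrambled virus, a pair on the same side of that split. Inflammatory genes were higher and cycle genes lower: the NF-kB list had a median of 3.42, or 3.07 with genes at 0 placed at their bound, with 14 of 15 members above 0, and the G2/M and S phase lists had -3.48 and -4.38, with all 51 and all 42 below 0. PDZK1IP1 had 1001 UMIs against 0, at least 271-fold higher, and GBP2, an interferon-induced GTPase, was at least 70.3-fold higher. SAA1, a serum amyloid, had 430 UMIs against 1, a log2 ratio of 8.45 (5.96 to 13.75), IL32, a cytokine, 8.22 (5.73 to 13.52), C15orf48 6.74 (6.04 to 7.55) and KRT17 6.39 (5.95 to 6.86). Immediate early genes had a median of 1.78, FOXO and quiescence genes 1.58, YAP and TGF-beta targets 1.51, interferon response 1.15 and mesenchymal genes 0.97. Glycolysis stood at -1.11, with 12 of 13 below 0, and MAPK output at -3.64, with 12 of 13 below 0. The ribonucleotide reductase subunit RRM2 was at -8.15 (-13.46 to -5.66), from 1 UMI against 230, and CDC6 was at least 66.2-fold lower. These medians lay outside at least 99.7% of random lists. Against the untreated library the G2/M median was -4.21, and that of p53 targets turned from 0.76 to -0.19.

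The library labelled KDM5A and KDM5B shRNA was set against the same scrambled library. Inflammatory, quiescence and immediate early genes were higher in it: the NF-kB list had a median of 3.10, or 2.71 with genes at 0 placed at their bound, with all 15 members above 0. The FOXO and quiescence list had 2.37, with all 13 above 0, immediate early genes 1.84, mesenchymal genes 1.10 and interferon response 0.92. PDZK1IP1 was at least 293-fold higher (493 UMIs against 0), SAA2 and GBP2 each at least 70.7-fold and MMP7 at least 49.3-fold. SAA1 was at 9.23 (6.74 to 14.54), from 337 UMIs against 1, C15orf48 at 6.43 (5.72 to 7.24), and SAT1, which acetylates polyamines, at 5.38 (4.93 to 5.87). G2/M genes had a median of -1.92 and S phase genes -4.11 (-3.46 with genes at 0 placed at their bound), all below 0, heat shock genes -1.003 and metallothioneins, which bind metals, -3.21 over 3 members, or -2.13 with genes at 0 placed at their bound. MCM6, a helicase subunit, was at least 30.3-fold lower, and ODC1, which starts polyamine synthesis, was at -4.76 (-6.08 to -3.70). Among random lists the percentiles of these medians ran from 0 to 0.360 and from 99.5 to 100. KDM5B was higher here, not lower as the label would have it, and the pair crosses the pseudogene split (2.38% against 1.31%), with no drug-free library on the high side.

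KDM5A cDNA with erlotinib was set against the scrambled library as well. Lipid synthesis genes were higher with KDM5A cDNA: the cholesterol synthesis list had a median of 1.61, with 19 of 21 members above 0 and a pooled ratio of 1.52 (1.41 to 1.63), and the fatty acid list 0.63, with 7 of 10 above 0. The medians of the same lists against the scrambled library were -0.49 and -0.71 with KDM5A shRNA and -0.44 and -0.66 with KDM5A and KDM5B shRNA, and the difference between arms was not tested. HMGCS1, of the mevalonate pathway, stood at 424 CPM against 88.8 CPM in scrambled cells, and SCD at 146 against 12.4 CPM. The NF-kB list had a median of 2.88, with all 13 members above 0, FOXO and quiescence 1.84 and interferon response 0.93, but the last was -0.05 over members with at least 50 UMIs. Immediate early genes had a median of 1.38 with 6 members above and 5 below 0, and a pooled ratio of 0.48 (0.28 to 0.68). The interferon-induced GTPases GBP1 and GBP2 were at 4.82 (3.63 to 6.31) and at least 24.1-fold higher, OLR1, a receptor for oxidised lipoprotein, at 5.86 (4.46 to 7.76) and IL32 at 6.59 (4.04 to 11.93), from 44 UMIs against 1. G2/M genes had a median of -2.17 and S phase genes -3.83 (-3.16 with genes at 0 placed at their bound), all below 0. CLSPN and CDK1, the mitotic kinase, were at 0 UMIs and at least 40.3-fold and 30.8-fold lower. The fatty acid median lay at the percentile 97.6 among random lists, the interferon median at 99.7 and the other medians outside at least 99.9% of them. Against the untreated library the cholesterol median was -0.22 and the fatty acid median -1.002, and KDM5A itself stood at 0.44. The pair crosses the pseudogene split (3.25% against 1.31%), with no drug-free library on the high side.

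KDM5A shRNA against KDM5A cDNA held erlotinib constant and set a library with KDM5A counted at 56.4 CPM against a library with it counted at 164 CPM. The vectors also differed, pLVTHM against pLenti, and erlotinib started 4 against 6 days after transduction. The differences between these libraries therefore cannot be assigned to the KDM5A level alone. Cholesterol and fatty acid synthesis were lower with KDM5A shRNA, with medians of -1.88 and -1.37 and with 20 of 21 and 10 of 10 members below 0. INSIG1, which holds the sterol sensor in place, was at -3.36 (-3.94 to -2.83), SCD at -3.16 (-3.85 to -2.51) and MSMO1, a sterol oxidase, at -2.69 (-3.14 to -2.25). The elastase inhibitor PI3 was at 5.02 (3.46 to 7.31), from 264 UMIs against 3, PDZK1IP1 at 3.95 (3.36 to 4.60), MMP7 at 3.79 (2.41 to 5.69) and the immediate early factor EGR1 at 3.56 (2.17 to 5.46). The NF-kB median was 0.75 (0.49 with cells thinned to 1000 UMIs, 1.08 with cells weighted equally), YAP and TGF-beta targets 0.82, with 16 of 17 above 0, mesenchymal genes 1.11 and G2/M genes -0.84. The lipid and G2/M medians lay below all 10000 random lists, and the others named above at least 99.9% of them. The pair crosses the pseudogene split (1.25% against 3.25%). In the added pair on the high side, KDM5A and KDM5B shRNA against KDM5A cDNA, the pooled ratios were -2.08 (-2.23 to -1.93) for cholesterol synthesis, 0.41 (0.25 to 0.57) for the NF-kB list and 0.09 (-0.03 to 0.20) for G2/M, which was not lower there, with INSIG1 at -3.81, SCD at -3.27, PI3 at 5.36, PDZK1IP1 at 4.06 and EGR1 at 3.16.

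**Figure D3:**
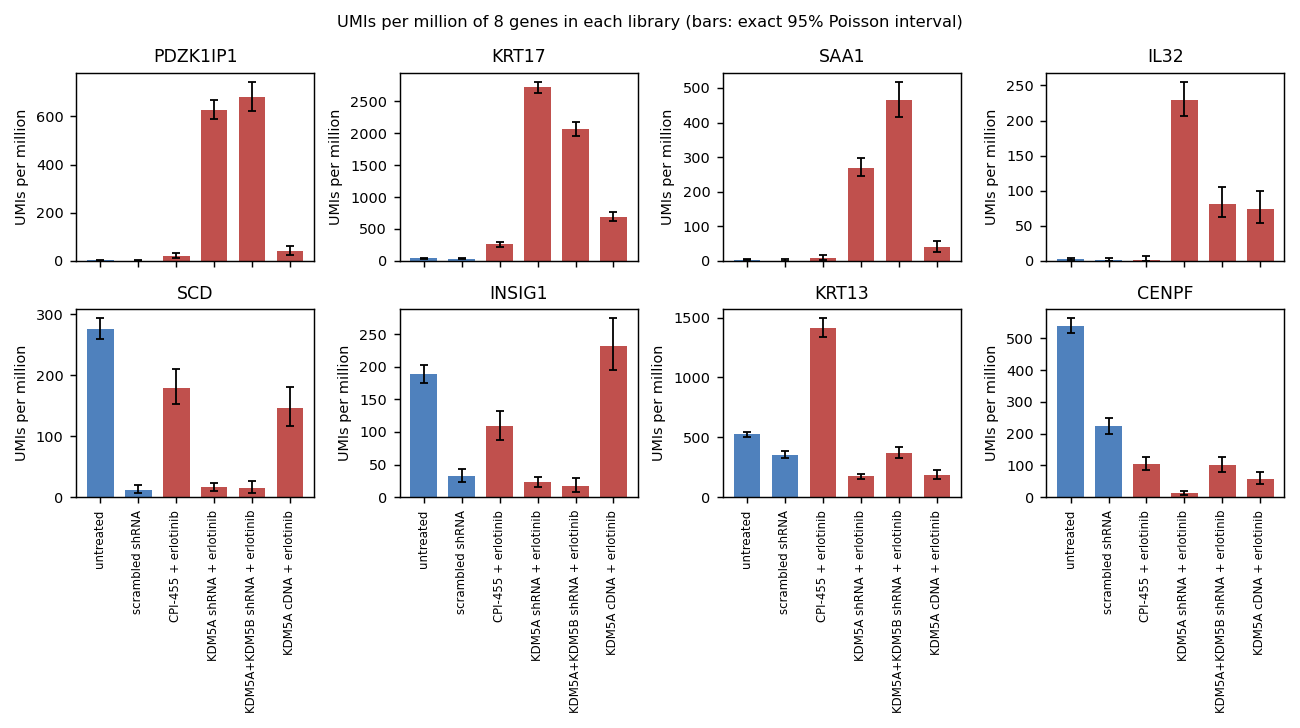
Levels of PDZK1IP1, KRT17, SAA1, IL32, SCD, INSIG1, KRT13 and CENPF in CPM, each gene on its own linear axis from 0, in each of the 6 libraries, 1 library per condition, with exact 95% Poisson intervals for counting error only. SCD stands at 276 CPM untreated, 179.7 with CPI-455 and 146 with KDM5A cDNA, and between 12.4 and 16.3 in the other 3 libraries.

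The library labelled KDM5A and KDM5B shRNA was set against KDM5A shRNA to ask what the added shRNA changed. Mitotic genes were higher and metallothioneins lower in it: the G2/M list had a median of 1.25, with 37 of 41 above 0, and the 4 metallothioneins a median of -2.77, or -1.61 with genes at 0 placed at their bound. CENPF, a kinetochore protein, was at 3.01 (2.28 to 3.80), MKI67, the Ki-67 antigen, at 2.35 (1.60 to 3.14) and PTTG1, or securin, at 1.97 (1.47 to 2.48). These intervals do not cover UMIs gathered in few cells. After thinning to 1000 UMIs, 6 of 124 cells held 44.8% of this library's G2/M UMIs, against 13.5% in 4 of 332 cells with KDM5A shRNA. Cells with at least 3 G2/M UMIs made up 16.1% (10.1 to 23.8) and 11.4% (8.23 to 15.4), with overlapping intervals. IGFBP5, which binds insulin-like growth factor, was at -2.94 (-3.92 to -2.11), the metallothionein MT2A at -1.84 (-2.36 to -1.36), IL32 at -1.50 (-1.92 to -1.10) and INHBA, an activin subunit, at -0.95 (-1.10 to -0.80). The NF-kB list had a median of -0.45, with 10 of 15 below 0, and the YAP and TGF-beta list -0.26. Among random lists these 4 medians lay at the percentiles 100, 0, 0.01 and 0.570. KDM5B did not differ beyond counting error, at -0.13 (-0.48 to 0.21). The pair crosses the pseudogene split (2.38% against 1.25%), and on the high side the pooled G2/M ratio of this library to KDM5A cDNA was 0.09 (-0.03 to 0.20) against 0.61 (0.51 to 0.70) for this pair. With cells thinned to 1000 UMIs the NF-kB median was 0.08 and CXCL1 turned from -1.45 to 0.42, for which no counting interval is given. Fewer cells remained in this library, 124 against 332. A list member with 0 UMIs in both thinned libraries therefore scores above 0 and can raise the median. These thinned values do not show a reversal. Without high-UMI cells the NF-kB median was -0.01, and over members with at least 50 UMIs it was -0.67. The lower NF-kB median therefore depended on the high-UMI cells.

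CPI-455 was set against KDM5A shRNA, an inhibitor of the enzyme family against an shRNA to KDM5A, both with erlotinib. Inflammatory and mesenchymal genes were lower with CPI-455: the NF-kB list had a median of -2.24, with 14 of 15 below 0 (-1.36 with cells thinned to 1000 UMIs, -1.57 without high-UMI cells), and mesenchymal genes -1.005. IL32 had 1 UMI against 367, a log2 ratio of -7.65 (-12.96 to -5.16), PDZK1IP1 was at -5.01 (-5.80 to -4.32), TAGLN, an actin-binding protein, at -5.10 (-6.42 to -4.04), SAA1 at -5.07 (-6.39 to -4.02) and INHBA at -3.81 (-4.17 to -3.48). Fatty acid and cholesterol synthesis were higher, with medians of 1.63 and 1.16 and with 10 of 10 and 21 of 21 members above 0, SCD being at 3.46 (2.86 to 4.12). The keratins KRT13 and KRT15 were at 3.01 (2.82 to 3.20) and 3.57 (2.68 to 4.58), and G2/M genes had a median of 0.99. These medians lay outside at least 99.9% of random lists. The pair crosses the pseudogene split (2.77% against 1.25%). CPI-455 cells also had no virus and 5% serum, while KDM5A shRNA and KDM5A cDNA cells were transduced and had 10%. Scrambled against untreated cells, which differed in the same way, had a cholesterol synthesis median of -2.11. Differences between these libraries therefore cannot be told apart from virus and medium. In the added pair on the high side, CPI-455 against KDM5A cDNA, pooled ratios were -1.14 (-1.35 to -0.94) for the NF-kB list, -0.84 (-0.95 to -0.74) for cholesterol synthesis, opposite in sign, 0.11 (-0.04 to 0.26) for fatty acid synthesis and 0.00 (-0.11 to 0.11) for G2/M, with KRT13 at 2.92, KRT15 at 3.72 and IL32 at -6.03, the last from 1 UMI.

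Across genes, the log2 ratios of CPI-455 against untreated were set beside those of each transduced erlotinib arm against scrambled, which share no library. Pearson's r was 0.764 for KDM5A shRNA over 3918 genes, 0.797 for KDM5A and KDM5B shRNA over 3996 and 0.813 for KDM5A cDNA over 3975, with Spearman's rho of 0.742, 0.801 and 0.793. These 3 relations are across genes, which are not independent replicates. CPI-455 against untreated crosses the pseudogene split (2.77% against 0.956%). So do KDM5A and KDM5B shRNA (2.38%) and KDM5A cDNA (3.25%) against scrambled (1.31%), while KDM5A shRNA (1.25%) does not. How far this shared crossing raises r was not tested.

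Single cells were then compared after thinning each to 1000 UMIs. Cells with at least 3 UMIs of G2/M genes made up 77.6% of 822 untreated cells (exact binomial 95% interval 74.6 to 80.4) and 87.8% of 222 scrambled cells (82.8 to 91.8). They made up 18.9% (13.2 to 25.7) with CPI-455, 11.4% (8.23 to 15.4) with KDM5A shRNA, 16.1% (10.1 to 23.8) with KDM5A and KDM5B shRNA and 22.9% (15.2 to 32.1) with KDM5A cDNA. For S phase genes the shares were 60.3% untreated, 82.4% scrambled and between 1.20% and 4.88% in the 4 erlotinib libraries. For NF-kB genes they were 16.9% (13 to 21.3) with KDM5A shRNA, 14.5% (8.84 to 22.0) with KDM5A and KDM5B shRNA, 5.71% (2.13 to 12.02) with KDM5A cDNA and 2.44% (0.668 to 6.13) with CPI-455, against 0.852% untreated and 0 of 222 scrambled cells, which allows up to 1.35%. At least 10 G2/M UMIs were found in 349 of 822 untreated cells and 48 of 222 scrambled cells, and in 5 of 164, 4 of 332, 6 of 124 and 5 of 105 erlotinib cells in the order given. The share with at least 3 depends on depth. At 2000 UMIs it was 36.4% to 48.9% with erlotinib, against 92.4% untreated and 99.4% scrambled. Not thinned, it was 55.0% to 66.4%, against 81.05% and 97.3%. All cells were of the same line, so no cell type gave a background level, and free RNA remains open in these shares.

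**Figure D4:**
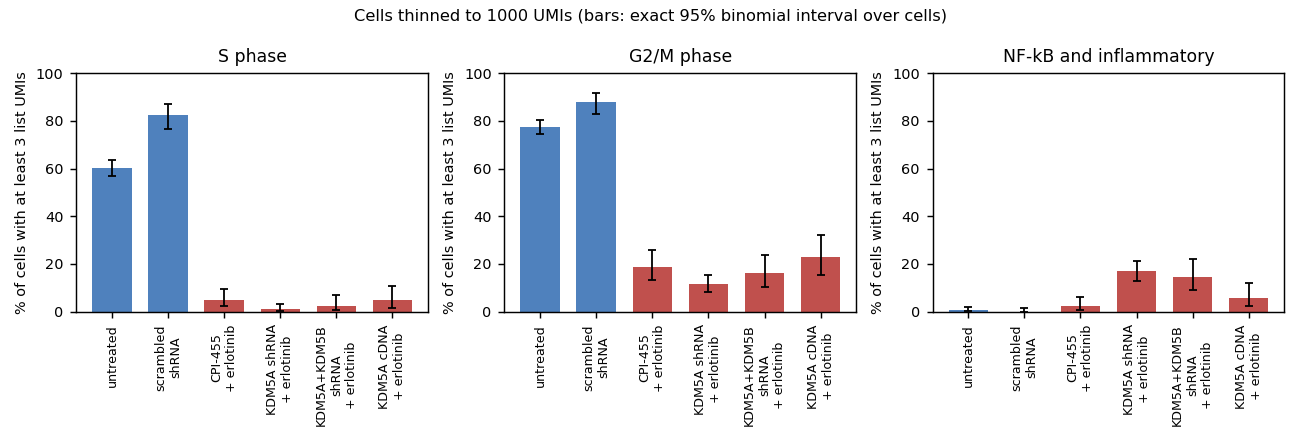
Percent of cells, thinned to 1000 UMIs, with at least 3 UMIs of the G2/M, S phase or NF-kB and inflammatory lists in each of the 6 libraries, 1 library per condition, with exact binomial 95% intervals over cells. G2/M shares lie between 11.4% and 22.9% with erlotinib and at 77.6% and 87.8% without.

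Within libraries, the genes that varied most between untreated cells beyond counting noise included mitotic genes. By excess squared coefficient of variation among 909 genes with a mean of at least 0.2 UMIs, CENPF ranked first at 2.26, and UBE2C, an ubiquitin ligase partner of mitotic exit, reached 1.69, TOP2A 1.59 and MKI67 1.56. ARL6IP1, ANLN, PRR11, PTTG1 and HMMR, also expressed in mitosis for the most part, were among the 15, with the surface protein TM4SF1 at 1.89, the chaperone HSPA5 at 1.34, and MT-ND4L, SPP1, SOX4 and GARS between 1.06 and 1.12. In the erlotinib libraries other genes ranked first: KRT17 at 6.32 with CPI-455, PI3 at 4.05 with KDM5A shRNA, MMP7 at 3.84 with KDM5A and KDM5B shRNA and INHBA at 2.997 with KDM5A cDNA. The mitotic genes named above, except ARL6IP1, had means under 0.2 UMIs in these libraries and could not be ranked. A change in what varied can therefore not be read from these ranks. KRT17, PI3 and MMP7 had means of 0.293, 0.208 and 0.210 UMIs, near that minimum, over 164, 332 and 124 cells. Of the 15 genes in untreated cells, 9 kept a place among 15 with cells thinned to 2000 UMIs, and ANLN, PRR11, PTTG1, MT-ND4L, SPP1 and GARS did not. At that depth UBE2C ranked first at 1.66, and CENPF had rank 7 at 1.38.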

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

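The tests of transduction alone, of transduction together with erlotinib, of erlotinib on pseudogenes, of parent genes and their copies, of a missing vector, of a knockdown masked by erlotinib and of other splits of the libraries were chosen after their results were seen, as were the added pairs on the high side of the pseudogene split.

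An entry named after the shRNA vector, pLVTHM, whose level the labels do not report, stood at 83.9 CPM with KDM5A shRNA (134 UMIs in 73 of 374 cells) and at 90.9 CPM with KDM5A and KDM5B shRNA (66 UMIs in 41 of 152 cells). It stood at 15.5 CPM in scrambled cells (20 UMIs in 11 of 263 cells) and at 0 in the CPI-455, KDM5A cDNA and untreated libraries, where no pLVTHM virus was used. Against the scrambled library, cholesterol synthesis moved in opposite directions in the shRNA and cDNA arms. The difference of medians was -2.10 for KDM5A shRNA minus KDM5A cDNA and -2.05 for KDM5A and KDM5B shRNA minus KDM5A cDNA, and for fatty acid synthesis it was -1.34 and -1.29. These differences between arms were not tested, and against the untreated library the cDNA medians were -0.22 and -1.002, so the opposite signs rest on the scrambled control.

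The NF-kB and inflammatory list was higher in the 3 transduced erlotinib libraries than in the CPI-455 library, with a median of -2.24 for CPI-455 against KDM5A shRNA. The tables argue against cells over 3 times the median UMIs as the whole source, since the median was -1.57 without them. Doublets under that limit stayed in, so doublets as such stay open. Transduction alone cannot be told apart: scrambled cells lay below untreated cells at a pooled -0.45 (-0.64 to -0.27), but they had 10% rather than 5% serum, and the KDM5A shRNA library carried 5.43 times their vector level (3.38 to 9.18). Cells with a vector UMI in the KDM5A shRNA library had 1.28 times the list share of those without (1.03 to 1.59, 119 and 347 UMIs in 70 and 262 cells), so vector load may contribute. The same cells had less KDM5A. A vector UMI was seen in 73 of 374 kept cells, and cells without such a UMI may carry the vector uncaptured. How much vector load contributes can therefore not be told. Transduction together with erlotinib cannot be told apart from the KDM5 manipulations, because 0 libraries had erlotinib without such a manipulation.

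Processed pseudogenes were higher in the CPI-455, the KDM5A and KDM5B shRNA and the KDM5A cDNA libraries. Depth per cell stays open: the median for KDM5A cDNA against KDM5A shRNA was 1.66 after thinning and 1.47 before. After thinning, 105 and 332 cells remained. A gene with the same count in both thinned libraries, 0 included, scores 1.66 from these cell numbers, so the thinned median does not measure pseudogene levels. Erlotinib stays open: KDM5A shRNA with erlotinib had a median of -0.13 (quartiles -0.68 to 0.31) against scrambled cells without it, but this is 1 library, and the other 3 with erlotinib were high. A different division of reads between parent genes and copies stays open as well, since the copy exceeded its parent by a median log2 of 1.14 over 290 pairs, above 0 in 96.2% of them, which follows in part from the pattern itself, while the parents' median was 0.25 and not below 0. The labels give no library batches, and apart from erlotinib no biological explanation was tested.

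KDM5B was not lower in the library labelled KDM5A and KDM5B shRNA. A library without the vector is argued against by pLVTHM at 90.9 CPM, which does not tell a KDM5A from a KDM5B virus. Too few cells with the vector cannot be told apart from an shRNA without effect, because KDM5B in cells with a vector UMI was 1.05 times that in cells without (0.68 to 1.62, 39 and 55 UMIs). KDM5B was higher with erlotinib over the 6 libraries, but no knockdown beneath that level was seen: it stood at 138 CPM here against 102 with CPI-455, 151 with KDM5A shRNA and 94.9 with KDM5A cDNA, 1.09 times these together (0.868 to 1.36). A partial knockdown stays open, since the ratio to KDM5A shRNA was 0.913 (0.715 to 1.16).

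For the erlotinib counts, the 15 splits of the 6 libraries into 4 and 2 are too few for a share under 0.05: the real split gave 2458 genes, the highest of the other splits 1, and 1 of the 15 splits gave as many as the real one.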

How the results depend on the processing

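Alternatives for the pseudogene split, thinning and high-UMI cells in the erlotinib counts and for 10 list UMIs were chosen after the data were seen. No paired analysis was possible because the groups have 1 library each and the labels pair none. Depth limits KDM5A, with 30 to 106 UMIs in the transduced libraries, and CXCL3 and CXCL6, with 27 and 38 UMIs over the erlotinib libraries. Of 314 alternatives for named erlotinib genes, 273 gave the same result, 41 a weaker one and 0 reversed. Of 1232 for genes between 2 libraries, 1032 stayed within counting error, 198 moved in the same direction and 2 reversed. Of 891 for list medians, 538 stayed, 344 moved and 9 reversed. The 6 for correlations and the 12 for KDM5 levels stayed.

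The count of genes higher with erlotinib was 479 in transduced libraries only, 473 with cells thinned to 1000 UMIs and 490 with the pseudogene split as a term, and the count lower was 856, 509 and 611. Fewer genes or libraries entered the first and the thinned fit. With each library left out in turn, 500 to 1176 genes were higher, with 520 without KDM5A and KDM5B shRNA, 639 without scrambled and 500 without untreated, and 860 to 1341 were lower, with 899 without KDM5A and KDM5B shRNA and 860 without scrambled. The lists called by camera numbered 18, between 15 and 18 with a library left out and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05.

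With cells thinned to 1000 UMIs, KDM5A against scrambled was 0.30 with KDM5A shRNA, -0.28 with KDM5A and KDM5B shRNA and 1.47 with KDM5A cDNA. Against the untreated library it was -1.10 with KDM5A shRNA and 0.44 with KDM5A cDNA. Thinned CXCL1 for KDM5A and KDM5B shRNA against KDM5A shRNA was 0.42, with no counting interval given. In the thinned list medians below, a member with 0 UMIs in both libraries scores the log2 ratio of their cell numbers. These medians therefore depend on how many cells remained.

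The cholesterol median of scrambled against untreated was -1.84 without high-UMI cells and -2.01 with cells weighted equally. The G2/M median for CPI-455 was -2.32 without high-UMI cells, -2.49 without mitochondrial and ribosomal genes, -2.20 thinned and -2.01 against the other control. For KDM5A shRNA it was -3.55 with all barcodes, -3.87 with cells weighted equally, -3.19 thinned and -4.21 against the other control. For KDM5A and KDM5B shRNA it was -2.09 with all barcodes, -2.13 without high-UMI cells, -2.01 weighted equally, -1.59 thinned and -2.78 against the other control. For KDM5A cDNA it was -2.07 without high-UMI cells, -1.87 weighted equally, -1.58 thinned and -2.87 against the other control. Against the other control, cholesterol and fatty acid synthesis turned to 0.80 and 0.73 with CPI-455 and to -0.22 and -1.002 with KDM5A cDNA, and p53 targets to -0.19 with KDM5A shRNA. Interferon response with KDM5A cDNA turned to -0.0483 over members with at least 50 UMIs.

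The NF-kB median for KDM5A shRNA against KDM5A cDNA was 1.08 weighted equally and 0.49 thinned. For KDM5A and KDM5B shRNA against KDM5A shRNA it was -0.01001 without high-UMI cells, 0.0769 thinned and -0.67 over members with at least 50 UMIs. In that pair cholesterol synthesis turned to 0.00496 without high-UMI cells and immediate early genes to 0.00368 thinned. For CPI-455 against KDM5A shRNA the NF-kB median was -1.57 without high-UMI cells, -1.61 weighted equally and -1.36 thinned.

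G2/M shares at 2000 UMIs, not thinned, at 2 list UMIs and at 10 list UMIs were 37.9%, 55.0%, 35.4% and 3.05% with CPI-455; 36.4%, 60.4%, 29.8% and 1.20% with KDM5A shRNA; 39.6%, 61.8%, 33.1% and 4.84% with KDM5A and KDM5B shRNA; 48.9%, 66.4%, 47.6% and 4.76% with KDM5A cDNA; 99.4%, 97.3%, 94.6% and 21.6% in scrambled cells; and 92.4%, 81.05%, 86.1% and 42.5% in untreated cells. Deeper cells and lower minimums raise such a share by construction. Of the 15 most variable genes 9 remained at 2000 UMIs. The cause of the other changes was not tested.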

Other observations

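All values here that compare cells with and without a vector UMI, or libraries by the added pairs, were chosen after the data were seen.

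Several genes of the fixed lists stood apart in the libraries with pLVTHM shRNA and erlotinib. TAGLN, an actin-binding protein of contractile cells, stood at 274 CPM with KDM5A shRNA and 153 CPM with KDM5A and KDM5B shRNA, 45.8 with KDM5A cDNA, 8.01 with CPI-455 and between 3.86 and 4.30 without erlotinib. IGFBP3, which binds insulin-like growth factors, stood at 4515 and 3438 CPM against 1434 to 1749 in the other erlotinib libraries and 239 and 349 without the drug. B2M, the light chain of class I antigen presentation, stood at 2233 and 2214 CPM against 1273, 1261, 644 and 828 CPM in the KDM5A cDNA, CPI-455, scrambled and untreated libraries. CALR, a chaperone of the endoplasmic reticulum, stood at 1574 and 1199 CPM with the shRNA vectors and between 439 and 769 CPM elsewhere. CPI-455 cells had the most KRT8, a simple epithelial keratin, at 2235 CPM against 877 to 1248 CPM in the other libraries.

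On the high side of the pseudogene split, immediate early genes were higher with CPI-455 than with KDM5A cDNA at a pooled log2 ratio of 1.06 (0.88 to 1.25), with EGR1 at 3.58 (2.16 to 5.50). Mesenchymal genes were at a pooled 1.35 (1.20 to 1.51) for KDM5A and KDM5B shRNA against KDM5A cDNA and at -0.54 (-0.73 to -0.36) for CPI-455 against KDM5A cDNA. Their medians over 8 members were 0.73 and -0.20. Antigen presentation was at a pooled 0.64 (0.54 to 0.75) and -0.09 (-0.21 to 0.02) in these pairs. Its medians were 0.14 over 4 members and -0.01 over 3. The pooled 0.64 thus mainly reflects B2M, at 2214 against 1273 CPM.

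In the KDM5A shRNA library, KDM5A in the 70 cells of at least 1000 UMIs with a vector UMI was 0.284 times its share in the 262 cells without (0.131 to 0.550, 10 and 79 UMIs), and KDM5B was 1.04 times (0.779 to 1.37). Cells with a vector UMI were deeper, at a median of 5993.5 against 3335.5 UMIs, and in the same library KDM5A in deep against shallow cells was 0.929 (0.566 to 1.58). In the KDM5A and KDM5B shRNA library the KDM5A ratio was 1.49 (0.657 to 3.36), from 14 and 14 UMIs. In that library deep cells had less KDM5B than shallow cells, at 0.471 (0.306 to 0.733), and cells with a vector UMI were deeper (median 5379 against 3958.5 UMIs), so the KDM5B ratio of vector cells is not free of depth.

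Markers of other cell types were at low levels. Of 13 blood cell markers 3 were in the files, and LYZ, FCER1G and CD14 stood at 1.69 CPM or less in every library. Of 12 fibroblast and endothelial markers 7 were in the files. The highest were CDH5, of endothelial junctions, at 11.3 CPM with KDM5A shRNA (18 UMIs, 6.68 to 17.8) and COL1A1, a collagen chain, at 6.89 CPM with KDM5A and KDM5B shRNA, and the 1 marker tested with erlotinib, CDH5, did not pass at 1.80 (SE 0.80, edgeR adjusted p = 0.127; 1 of 1 adjusted over the list alone).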
